A study of Danio rerio with 6 samples.

How the data were processed

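RNA sequencing libraries labelled as liver of wild-type AB zebrafish were used, 3 from a control group and 3 from a group treated with graphene oxide. Group and replicate number were taken from the labels. The labels do not say that the replicates were separate animals or pools, so p-values measure only the spread between these libraries, which may be technical. No dose or exposure time was used.

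Each library had 1 table of 43106 rows with a gene ID, a symbol and 3 measures. The deposited expected counts are estimated counts per row that need not be whole, as the values themselves showed. Per the file headers, the deposited TPM and FPKM values are expression levels normalized for length and depth. TPM summed to 1000000 in every library. Per the submitters' processing notes, Bowtie2 2.3.2 was used with the GRCz11 assembly. The program that estimated the counts, its settings and its use of strand are not given in the sources used here. Estimated counts divide reads that match several genes, so values of close paralogs, overlapping genes and antisense partners are uncertain. Of the named genes, pcdh1g3, nme2a, gstp2, abcc6b.2, apoa4b.1 and rbp7a had a count that was not whole in at least 1 library.

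Of 36191 distinct gene IDs, 5932 stood on 2 to 6 rows, and these rows were summed. They held 23.2% to 24.1% of a library's counts. In the reference gene table, 30570 of the IDs were found. That table follows the assembly GRCz12tu, a different build, so it served only for names and no coordinates are given. The symbols try and ba1 in the tables are the older names of prss1 and hbba1.

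Total expected counts were 9739760 to 12998273 per library. A count of 0 allows up to 3 counts, which is 0.231 to 0.308 CPM (counts per 1000000 counts of a library) depending on the library. Shares of counts carry 95% Wilson intervals. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

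The tables were first assumed to hold FPKM alone, with limma as the test. Because expected counts were present, the gene test became edgeR's quasi-likelihood test on expected counts rounded to whole numbers, as laid down for that case before the data were examined. Genes needed a mean FPKM of at least 1 over the 6 libraries, which left 19313. Library sizes were scaled by TMM, and the fit had the group as its only term. Gene values are TMM-scaled CPM, and list totals are unscaled CPM over all counts. Log2 values per library used a prior count of 2. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and tests were two-sided.

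Gene lists were tested with camera from limma on log2(FPKM + 1), with a preset correlation of 0.01 between genes. Of 41 lists fixed before the data were examined, 37 had at least 5 measured members. A further 9 lists of tissue and clock genes were written after the data were examined and adjusted separately. Members are counted as past the gene test over all genes tested or adjusted over the list alone.

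Genes were named by a rule fixed before the data were examined. It took the genes past the threshold with groups that did not overlap or, with none, the 5 smallest p-values in each direction among genes with non-overlapping groups and a real symbol. It added up to 4 members of each list past the list test and a set of immune, lipid, oxidative stress and cell marker genes given whatever their values. For replicates 1 and 2, the 10 called genes with the largest log2 fold change in each direction and a mean of at least 10 CPM in either group were named by a rule chosen after the data were seen. The genes mmp9, socs3a, prdx1, fosl1a and mt2 were also chosen after their values were seen.

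Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means across genes. It was 0.73 for replicate 1, 0.75 for replicate 2 and 0.87 for replicate 3, each above the limit of 0.1, so the numbers were taken to pair the libraries. The pairing comes from the data, since the labels give a number only. Replicates 1 and 2 also correlated across numbers at 0.72 and 0.74, and within control and graphene oxide at 0.67 and 0.73. All these lie high because replicate 3 lay far from them in both groups. The check therefore set replicate 3 apart but could not tell which of replicates 1 and 2 belong together. Counts of replicates 1 and 2 of a group were compared by chi-square over genes with at least 10 counts in the pair. The chi-square per degree of freedom was 1.62 for control and 1.56 for graphene oxide, more than sampling noise gives, so they were counted as separate libraries.

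Alternatives chosen before the data were examined covered pseudocounts, filters, scalings, a replicate block, a vitellogenin covariate, variance models, thresholds, set tests and leaving out each library. DESeq2, limma on FPKM, a fit of replicates 1 and 2 alone and the test of the difference between that effect and the one in replicate 3 were chosen after seeing the data. The lone replicate 3 library of each group was assumed to vary like the others in that last test.

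The functions were tested on simulated data with the 19313 genes, 200 of them changed. With the spread of all 6 libraries, the main test recovered 1% of genes changed 2-fold and 54% of those changed 4-fold. Another simulation set the levels of replicate 3 apart, with equal effects in all pairs and the spread of replicates 1 and 2. The test then recovered 11% and 47% without a block and 93% and 100% with it, where 11 unchanged genes were also called. The common dispersion, edgeR's measure of spread, was 0.000716 there, against 0.0140 for the block fit of the data. Recovery with the block in the data is therefore not known from it. For replicates 1 and 2 alone, recovery was 89% and 100%, with 4 unchanged genes called. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.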

Results

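Gene expression was measured by RNA sequencing in 6 libraries labelled as liver of 3-month-old AB zebrafish, a common wild-type laboratory strain. There were 3 libraries from untreated controls and 3 from fish given graphene oxide, a sheet-like carbon nanomaterial. The study's title places the question in liver function and innate immune signalling. Total expected counts ranged from 9739760 to 12998273 per library.

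The most abundant transcripts in these libraries were those of skeletal muscle and skin rather than those of hepatocytes. The fast myosin heavy chain gene myhz1.1 averaged 13806 CPM (counts per 1000000 counts of a library), the muscle-expressed actin gene actc1b 13464 CPM, the keratin gene krt4 10299 CPM and the calcium buffer gene pvalb2 8340 CPM. A list of 45 muscle genes took 8.62% (95% Wilson interval 8.61% to 8.64%) to 12.3% (12.2% to 12.3%) of a library's counts. A list of 29 hepatocyte genes took 0.0704% (0.0689% to 0.0719%) to 1.65% (1.64% to 1.66%). Lists of epidermis, photoreceptor, neural and lens genes reached 29079, 11083, 10878 and 7798 CPM in their highest library. Embryonic and larval globins, the oxygen carriers of young fish, took 1101 to 1866 CPM, while the 4 adult globin genes had 5 counts in all 6 libraries together. The adult globin gene ba1 had 1 count over all libraries. The muscle, epidermis, eye, neural, lens and globin lists were written after the data were examined.

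**Figure D1:**
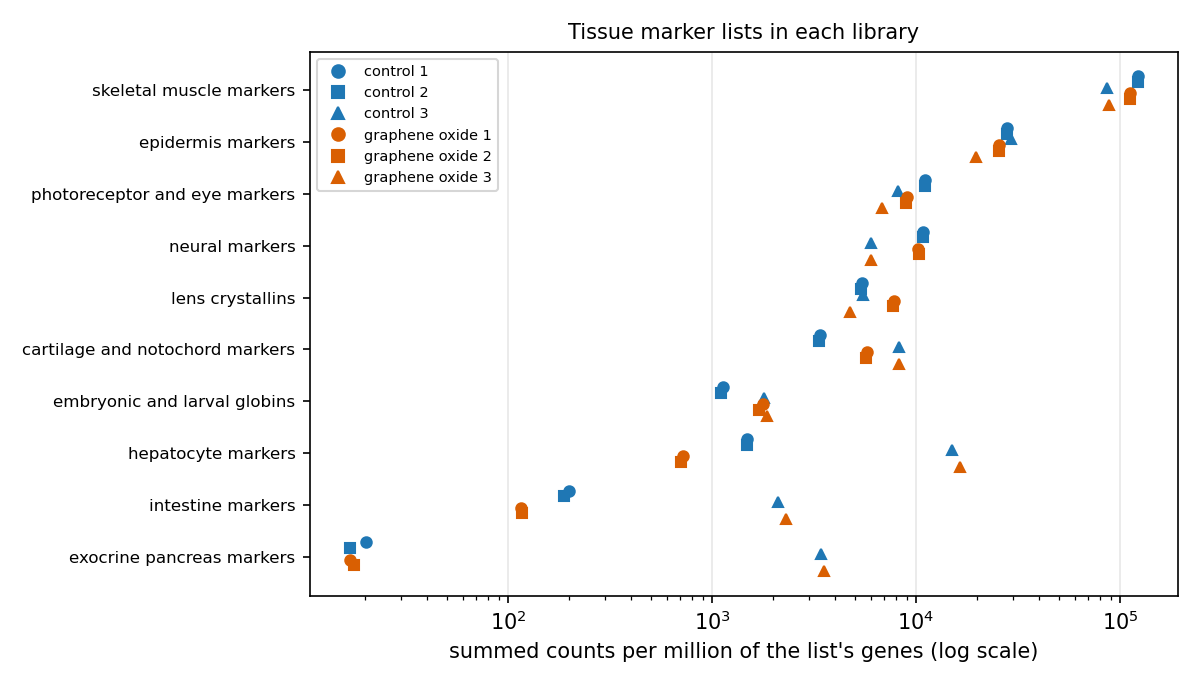
Summed CPM (horizontal log axis) of the genes in 10 tissue marker lists, with 1 point per library, controls in blue and graphene oxide in orange, and the marker shape giving the replicate number. The muscle list lies between 86247 and 122623 CPM in every library, and the hepatocyte, intestine and exocrine pancreas lists lie far higher in replicate 3 of both groups than in replicates 1 and 2.

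Replicate 3 of both groups stood apart from replicates 1 and 2 in its digestive organ transcripts. The hepatocyte list was at 14969 CPM in control replicate 3 against 1484 and 1479 CPM in control replicates 1 and 2, and at 16475 against 719 and 704 CPM with graphene oxide. The exocrine pancreas list, digestive enzymes for the most part, was at 3429 and 3561 CPM in the replicate 3 libraries and at 16.7 to 20.1 CPM in the others. The intestine list was at 2103 and 2317 CPM against 116 to 199 CPM. The liver fatty acid-binding protein gene fabp10a was at 117 and 119 CPM in replicate 3 and at 1.03 to 1.59 CPM elsewhere, and the trypsin gene try was at 498 and 516 CPM against 1.11 to 2.54 CPM. The neural list was at 5986 and 6017 CPM in replicate 3 against 10226 to 10878 CPM. Across genes, which are not independent replicates, the Spearman correlation of log2 CPM was 0.99 between replicates 1 and 2 of either group and 0.99 between the replicate 3 libraries. It was 0.87 to 0.89 between replicate 3 and the others. The first principal component held 81.5% of the variance and separated replicate 3, and the second held 10.3% and separated the groups among replicates 1 and 2.

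**Figure D2:**
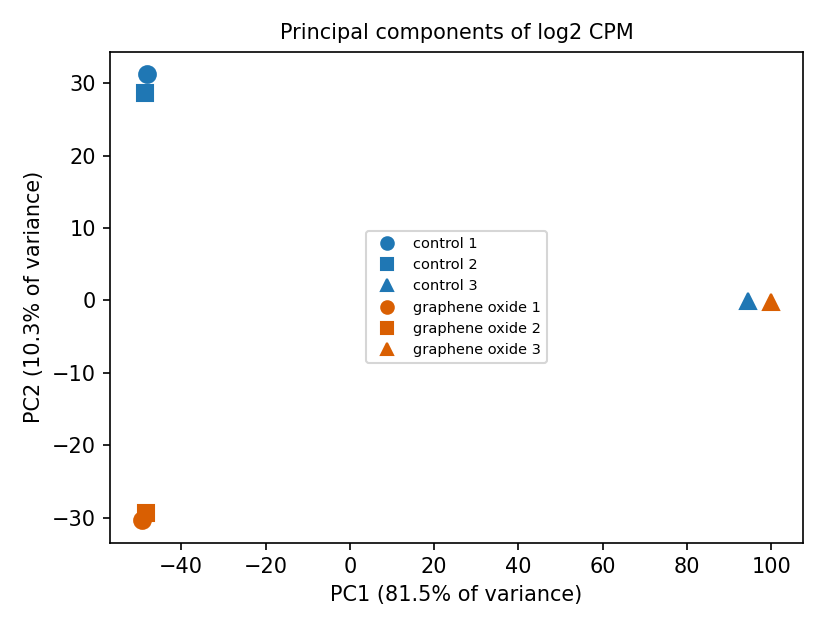
First (horizontal) and second (vertical) principal components of log2 CPM over the tested genes, with 1 point per library, controls in blue and graphene oxide in orange. The replicate 3 libraries lie at 94.5 and 99.9 on the first axis and the others between -49.3 and -48.2, and the second axis separates the groups among replicates 1 and 2 only, at 28.6 and 31.3 against -30.3 and -29.3.

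The comparison of graphene oxide with control over all 6 libraries gave no gene past the threshold, and the genes with the smallest p-values are given here as not past it. The low-density lipoprotein receptor gene ldlrb (gene ID 393460) was at 62.3 ± 7.82 CPM with graphene oxide and 32.5 ± 0.887 CPM in control (SD, n = 3 each), a log2 fold change of 0.94 ± 0.13 (SE). The sterol synthesis gene cyp51 (414331) was at 19.9 ± 2.23 against 11.5 ± 1.43 CPM, and the immediate early transcription factor gene junba (407086) at 44.7 ± 4.55 against 23.9 ± 5.34 CPM. The solute carrier gene slc16a9a (795588) was at 13.5 ± 1.93 against 7.63 ± 0.786 CPM, and the chemokine gene ccl34a.4 (100170820) at 1.91 ± 0.149 against 0.550 ± 0.149 CPM. In the other direction, the protocadherin gene pcdh1g3 (553987) was at 8.43 ± 1.98 against 64.3 ± 30.0 CPM, a log2 fold change of -2.93 ± 0.45 (SE). The green cone opsin gene opn1mw1 (30503) was at 555 ± 52.6 against 810 ± 12.1 CPM. The nucleoside diphosphate kinase gene nme2a (335716) was at 18.4 ± 0.441 against 35.9 ± 6.70 CPM, rgcc (431737) at 53.3 ± 3.51 against 77.7 ± 1.93 CPM and setd7 (436729) at 23.9 ± 0.711 against 34.5 ± 2.15 CPM. The counts of pcdh1g3 and nme2a were not whole in at least 1 library, a sign of reads divided between similar genes, so they are uncertain. opn1mw1 also has close paralogs, but its counts were whole.

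The quasi-likelihood test of edgeR called 0 of 19313 genes, with a smallest adjusted p of 0.99988, and 438 genes (2.27%) had an unadjusted p under 0.05. With the replicate number as a block it again called 0 genes, with a smallest adjusted p of 0.16, while 2793 genes (14.5%) were under the unadjusted level. limma on log2(FPKM + 1) called 0 genes with and without the block, with 2835 and 550 under the unadjusted level. DESeq2 called 10 genes, of which ldlrb, irg1l and si:ch211-207n23.2 were higher and 7 were lower, pcdh1g3, nme2a, opn1mw1 and rgcc among them, and 61 with the block. Weighting libraries by quality in limma gave 1956 genes. With these weights the fibroblast and ribosomal list medians were 0.42 and -0.34, close to 0.43 and -0.35 for replicates 1 and 2 alone. Without weights they were 0.26 and -0.25. The 1956 genes may therefore rest largely on replicates 1 and 2, whose spread was small. The groups did not overlap for 1498 genes (7.76%), where chance gives 10% for libraries that vary alike, which these did not. Of all genes 37.7% had the same direction in the 3 same-numbered pairs.

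Over the fixed gene lists, transcripts of cytosolic ribosomal proteins and of nuclear-encoded oxidative phosphorylation subunits fell with graphene oxide, and those of cholesterol synthesis, fibroblast and endothelial genes rose, in a set test with a preset correlation. With an estimated correlation none of these calls held in camera. The adjusted p was then 0.868 for the first 2 lists and 0.988 for the other 3. All 81 measured ribosomal protein genes had a negative log2 fold change, with a median of -0.26. For example, rpl39 was at 500 ± 49.1 against 706 ± 108 CPM, rps28 at 379 ± 37.7 against 533 ± 71.3 CPM, rpl36 at 500 ± 38.7 against 663 ± 56.4 CPM and rps21 at 458 ± 37.4 against 607 ± 46.9 CPM (SD, n = 3 each). Of 86 oxidative phosphorylation genes 81 were lower, with a median of -0.24, among them uqcrb of complex III at 111 ± 9.19 against 157 ± 22.4 CPM and the ATP synthase gene atp5e at 79.9 ± 11.2 against 112 ± 9.57 CPM. The complex I gene ndufa1 was at 50.8 ± 3.47 against 67.9 ± 6.12 CPM and the cytochrome oxidase gene cox4i2 at 30.1 ± 2.1 against 39.8 ± 2.45 CPM.

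Of 29 measured cholesterol synthesis genes 25 were higher, with a median log2 fold change of 0.22. Beside ldlrb and cyp51, the squalene epoxidase gene sqlea was at 4.68 ± 2.28 against 2.1 ± 0.347 CPM and the mevalonate pathway gene pmvk at 3.14 ± 0.430 against 2.16 ± 0.310 CPM. Of 32 stellate and fibroblast genes 26 were higher (median 0.21). The collagen genes col1a1a, col1a2 and col1a1b were at 3611 ± 187, 1452 ± 59.5 and 1809 ± 134 CPM against 3030 ± 431, 1248 ± 251 and 1596 ± 264 CPM, and the protease inhibitor gene timp2b at 16.7 ± 2.94 against 9.73 ± 3.68 CPM. Of 27 endothelial genes 23 were higher (median 0.19), with fli1a at 30.3 ± 8.37 against 20.5 ± 10.9 CPM, sox7 at 18.9 ± 9.91 against 12 ± 0.96 CPM, aplnra at 16.4 ± 1.90 against 11.8 ± 1.87 CPM and the scavenger receptor gene stab2 at 19.6 ± 1.15 against 16.1 ± 2.67 CPM. No member of these 5 lists passed the gene test over all genes. Adjusted over the list alone, the 2 cholesterol genes ldlrb and cyp51 passed and none of the other 4 lists' members did. With the replicate block, 4 fibroblast members (fn1a, fn1b, timp2b and fbln5) and 2 endothelial members (fli1a and vsg1), all higher and named after their values were seen, passed as well.

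The adjusted p from camera over 37 lists was 2.52e-50 for ribosomal proteins, 3.24e-28 for oxidative phosphorylation, 3.77e-05 for cholesterol synthesis, 0.0255 for fibroblast and 0.037 for endothelial genes. The replicate block gave 9 lists, adding higher erythrocyte (adjusted p = 0.00167) and antioxidant (0.00901) lists and lower hepatocyte (0.000214) and intestine (0.000574) lists. With the block and an estimated correlation camera gave 0 lists, at a smallest adjusted p = 0.711. In fry 0 passed with and without the block. Without control replicate 3, 15 lists were higher and 2 lower. Without graphene oxide replicate 1 or replicate 2, 10 were higher and 2 lower, and without graphene oxide replicate 3, 0 were higher and 13 lower, so that the cholesterol, fibroblast and endothelial lists were no longer past the threshold as higher. The fibroblast and endothelial calls also ended without control replicate 1 or control replicate 2. Each of these fits has unequal shares of replicate 3 in the groups, and those without a replicate 3 library have it in only 1 group. Their group term therefore takes in part of the difference of replicate 3 from the others. On log2(FPKM + 1), where the ribosomal and oxidative phosphorylation medians were -0.25 and -0.22, they were -0.02 and -0.15 with quantile normalization and -0.12 and -0.10 with TPM, still past the threshold as lower. In the replicate 3 pair the medians of the ribosomal, oxidative phosphorylation, fibroblast and endothelial lists were 0.01, 0.01, 0.03 and 0.04, against -0.38, -0.33, 0.42 and 0.36 in the replicate 1 pair. The cholesterol medians were 0.23, 0.05 and 0.23 in pairs 1, 2 and 3.

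**Figure D3:**
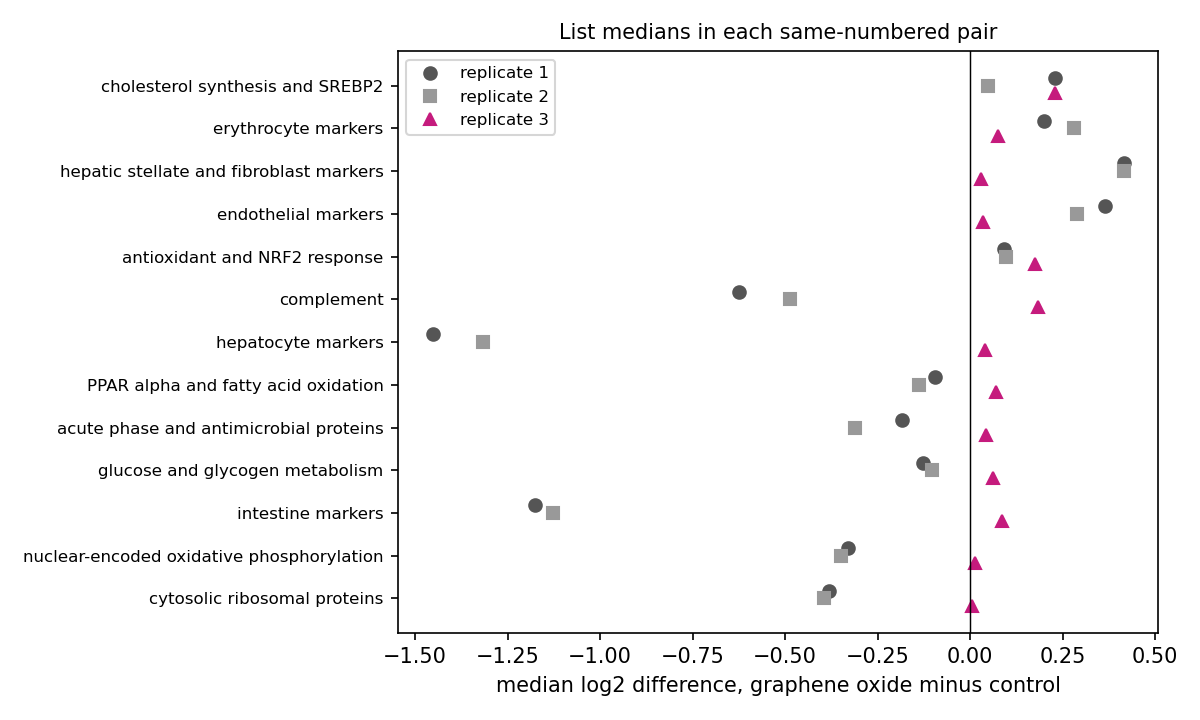
Median log2 difference in CPM, graphene oxide minus control (horizontal axis), in each same-numbered pair of libraries, for the 13 fixed lists past the threshold over all libraries, with the replicate block or among replicates 1 and 2. Points are medians over the measured members of a list, and the replicate 3 medians of the ribosomal and oxidative phosphorylation lists lie at 0.01 where those of replicate 1 lie at -0.38 and -0.33.

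Transcripts of innate immune signalling, the subject named in the study's title, did not pass over all 6 libraries. These libraries held far more muscle than hepatocyte transcripts. The main test recovered 1% of simulated 2-fold changes with the spread of all 6 libraries and 11% with replicate 3 set apart. The result therefore does not show that immune signalling in liver was unchanged. The 6 lists of Toll-like receptors, NF-kB pathway, cytokines, chemokines, interferon response and antigen presentation held 92 list members, none past the gene test over all genes and 1, ccl34a.4, adjusted over the list alone. In the 3 controls ccl34a.4 was at 0.424, 0.715 and 0.510 CPM, not far above what 0 counts allow. The adjusted p of the 6 lists from camera was 0.267 to 0.99. The median log2 fold changes of these lists ran from -0.08 to 0.28, the highest for cytokines and their receptors. The cytokine gene il1b was at 1.51 ± 0.565 with graphene oxide and 1.34 ± 0.327 CPM in control (SD, n = 3 each), and the neutrophil attractant cxcl8a at 1.59 ± 0.426 against 1.16 ± 0.128 CPM. The adaptor gene myd88 was at 8.20 ± 0.244 against 6.11 ± 3.93 CPM, and the NF-kB inhibitor gene nfkbiaa at 21.7 ± 5.66 against 26.1 ± 2.0 CPM. The tumour necrosis factor gene tnfa had 0 counts in every library, which allows up to 0.308 CPM in the shallowest, and the acute phase gene saa had at most 2 counts in a library.

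Complement, coagulation and acute phase lists had adjusted p-values of 0.45 to 0.962, and macrophage, neutrophil and T cell lists of 0.268 to 0.842. With the replicate block, 6 macrophage members, 5 of them higher, and the higher neutrophil members mmp9 and srgn passed when adjusted over the list alone, the last 2 named after their values were seen. The neutrophil gene mpx was at 14.2 ± 12.1 against 8.40 ± 3.41 CPM and the macrophage gene mpeg1.1 at 7.31 ± 3.21 against 6.48 ± 3.16 CPM. The antioxidant genes sod1 and cat were at 84.4 ± 39.8 and 89.7 ± 59.15 CPM against 84.1 ± 27.7 and 89.7 ± 49.96 CPM. The lipid sensor genes pparaa and pparab were at 12.6 ± 4.02 and 5.69 ± 4.37 against 11.57 ± 4.35 and 4.41 ± 3.68 CPM. The egg yolk precursor gene vtg1 had at most 12 counts in a library. Over the 32 lists that did not pass, adjusted p ran from 0.0981 to 0.99. The hepatocyte list had a camera direction of lower but a median log2 fold change of 0.03 in the count fit.

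Among replicates 1 and 2, taken without the replicate 3 libraries after seeing the data, many genes differed between graphene oxide and control. These libraries may be repeats of 1 pool per group, so the rises and falls given here need not come from the treatment. The inducible cyclooxygenase gene ptgs2b (559020) rose from 11.13 and 8.89 CPM in control to 125 and 123 CPM, and irg1l (562007) from 5.83 and 5.4 to 106 and 109 CPM. The clock repressor genes per1a (563926) and nr1d1 (494487) rose, with log2 fold changes of 2.99 ± 0.16 and 2.95 ± 0.10 (SE). The pituitary hormone gene smtlb, the serine protease gene prss60.2, the early response gene egr2a, ponzr3, the glutathione transferase gene gstp2 and the transporter gene abcc6b.2 rose by 5.99, 2.93, 2.67, 2.56, 2.49 and 2.41 on the log2 scale. The bile acid-binding protein gene fabp6 (415166) fell from 23.3 and 22.6 to 0.924 and 1.34 CPM, and cyp1a (140634), a target of the aryl hydrocarbon receptor, from 24.9 and 24.0 to 2.77 and 3.08 CPM. The plasma and lipoprotein genes apoa4b.1, fetub and apoa2 had log2 fold changes of -2.39, -2.36 and -2.18, and epdl2, rbp7a, the aminopeptidase gene anpepb, s100a10a and pcdh1g3 of -2.51, -2.09, -2.04, -1.95 and -3.44. The counts of gstp2, abcc6b.2, apoa4b.1, rbp7a and pcdh1g3 include reads divided between similar genes.

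In the same libraries, myd88 rose from 4.13 and 3.57 to 7.95 and 8.21 CPM (adjusted p = 1.97e-05, edgeR), and nfkbiaa fell from 24.2 and 26.0 to 18.2 and 18.7 CPM (0.00117). The gelatinase gene mmp9, the cytokine signalling inhibitor gene socs3a, the peroxiredoxin gene prdx1 and the AP-1 gene fosl1a rose by 1.76, 1.2, 0.98 and 2.6 on the log2 scale, and the metallothionein gene mt2 had a log2 fold change of -0.74. In the replicate 3 pair the log2 differences of myd88, nfkbiaa and socs3a were -0.33, 0.004 and -0.06. Those of mmp9, prdx1, fosl1a and mt2 were 0.27, 0.32, 0.82 and -0.31. Of the 92 innate immune list members, 18 rose and 9 fell, where 2491 of all 19313 tested genes rose and 2319 fell. None of the 6 lists passed camera among replicates 1 and 2, at adjusted p = 0.0845 to 0.92. The complement and acute phase lists did pass camera there as lower, at adjusted p = 0.000221 and 0.00203, and coagulation did not (0.216). With an estimated correlation complement and acute phase did not pass either, at adjusted p = 0.322 and 0.354. Of 25 hepatocyte genes 15 fell and 2 rose, of 27 complement genes 14 fell and 1 rose, and of 21 intestine genes 11 fell and 1 rose. Of 81 ribosomal protein genes 79 fell, and of 86 oxidative phosphorylation genes 75 fell. Of 32 fibroblast genes 23 rose and 4 fell, and with them 20 of 28 cartilage and notochord genes, a list written after the data were examined, rose and 1 fell. The hepatocyte list total in these libraries was 719 and 704 CPM with graphene oxide against 1484 and 1479 CPM in control.

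The edgeR quasi-likelihood test of replicates 1 and 2 called 4810 genes, 2491 higher and 2319 lower, of which 368 and 242 changed at least 2-fold. Its spread was that between replicates 1 and 2 alone, which had a chi-square per degree of freedom of 1.62 in control and 1.56 with graphene oxide. The common dispersion was 0.000716, against 0.166 over all 6 libraries. Such a small spread may be technical or that of 1 pool, so the p-values do not measure spread between separate fish. With library totals in place of TMM the split was 3295 higher and 1654 lower. DESeq2 called 2047 genes and limma 2468. Without graphene oxide replicate 2 the count was 3037. Of the 37 fixed lists, camera gave 11 past the threshold and 0 with an estimated correlation. With it the adjusted p of the ribosomal list was 0.346 and that of oxidative phosphorylation 0.124. Of the lists written after the data were examined, the eye, lens, cartilage and clock lists passed camera with an estimated correlation, each at adjusted p = 0.0356.

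The replicate 3 pair, a single library per group with no test of its own, repeated these differences only in part. In that pair ptgs2b was at 14.4 CPM with graphene oxide against 21 CPM in control, irg1l at 14.7 against 14.9 CPM, cyp1a at 52.8 against 48.9 CPM and fabp6 at 85.1 against 53.8 CPM. The clock genes per1a and nr1d1 lay the other way, at 19.7 against 43.2 CPM and 59.22 against 125 CPM. pcdh1g3, ldlrb and nme2a lay in the direction of the other pairs, at 10.1 against 30.2, 53.3 against 31.6 and 18 against 28.5 CPM. Of the 4810 genes called among replicates 1 and 2, 54.6% had the same direction in the replicate 3 pair, as did 51.7% of the 14503 genes not called, and of the 610 with at least a 2-fold change 42.8% did. The Spearman correlation across genes of the fold changes was 0.06. The difference between the effect in replicates 1 and 2 and that in replicate 3 passed edgeR's test for 2746 genes, with the lone libraries assumed to vary as little as replicates 1 and 2 did.

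**Figure D4:**
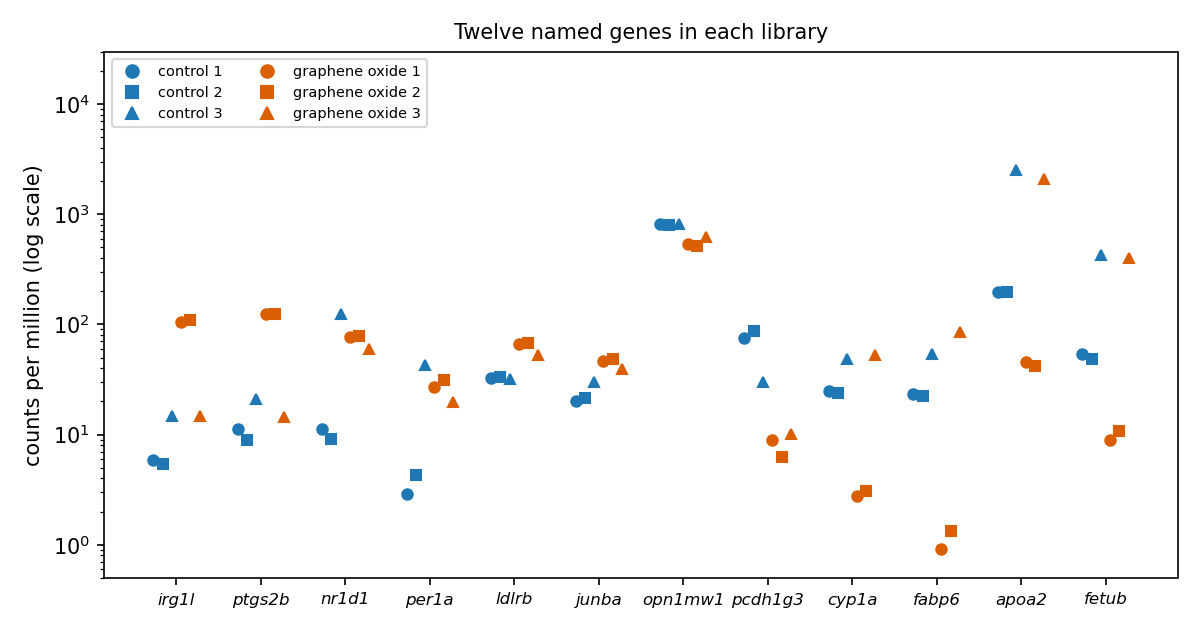
CPM (vertical log axis) of 12 named genes, with 1 point per library, controls in blue and graphene oxide in orange, and the marker shape giving the replicate number. For ptgs2b, graphene oxide replicates 1 and 2 lie at 125 and 123 CPM and replicate 3 at 14.4 CPM, while ldlrb lies at 53.3 to 67.4 CPM in the 3 graphene oxide libraries and at 31.6 to 33.4 CPM in the controls.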

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

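The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries, which were planned.

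A test of the difference between the graphene oxide effect in replicate 3 and that in replicates 1 and 2 passed for 2746 genes, and 41 of the 64 named genes were among them. Replicate 3 has 1 library per group, so all the spread came from replicates 1 and 2, which differed little (chi-square per degree of freedom of up to 1.62), and the number is too high if replicate 3 libraries vary more. Values here are the log2 effect in replicate 3 minus that in replicates 1 and 2. They were positive for cyp1a (3.16), fabp6 (4.97), epdl2 (2.66), apoa4b.1 (2.64), rbp7a (2.33), anpepb (2.29), fetub (2.27), apoa2 (1.91), pcdh1g3 (1.86), s100a10a (1.75), mpx (1.01), mt2 (0.43), sod1 (0.31) and opn1mw1 (0.20). The ribosomal and oxidative phosphorylation genes rps21, rpl36, rps28, rpl39, uqcrb and atp5e had 0.39, 0.41, 0.58, 0.63, 0.57 and 0.55. They were negative for smtlb (-7.72), irg1l (-4.28), ptgs2b (-4.20), per1a (-4.13), nr1d1 (-4.02), abcc6b.2 (-3.29), ponzr3 (-3.20), prss60.2 (-2.58), egr2a (-2.48), gstp2 (-1.78), fosl1a (-1.77), sox7 (-1.56), mmp9 (-1.49), myd88 (-1.41), socs3a (-1.26), junba (-0.78) and prdx1 (-0.65). The collagen and vessel genes col1a1b, col1a2, fli1a and col1a1a had -0.58, -0.58, -0.58 and -0.47. The size of the smtlb value is uncertain, because some levels behind it lay near what 0 counts allow. They were 0.106 and 0.318 CPM in control replicates 1 and 2 and 0.275 CPM in graphene oxide replicate 3.

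Libraries labelled adult liver held far more muscle than hepatocyte transcripts. A minor part of other tissue carried over into adult liver needs hepatocyte transcripts to lead, and the lowest ratio of muscle to hepatocyte list counts in a library was 5.39. RNA from whole embryos or larvae is a candidate explanation, since embryonic and larval globins took at least 99.985% of globin counts in every library, where adult fish use other globin genes. Whether the tables belong to other samples than the labels say stays open. These transcripts were found in both groups, and no explanation by treatment was tested.

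Replicate 3 of both groups differed from replicates 1 and 2. Depth did not account for it, because at equal depth the highest Spearman correlation of replicate 3 with the others was 0.888 and the lowest among replicates 1 and 2 was 0.978. More digestive organ RNA alone would change other tissues by a common ratio, yet the cartilage list's change was at least 2.47 times the neural list's in both groups. A later developmental stage of replicate 3 may be a cause. The hepatocyte, pancreas, intestine and cartilage lists were all higher, with a smallest ratio of 1.45. The first 3 lists had already set replicate 3 apart, so they cannot test this. The cartilage list alone, at ratios of 2.45 in control and 1.45 with graphene oxide, does not decide it. A separate batch of fish or libraries cannot be told apart from a later stage, as the labels give no batch.

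The graphene oxide difference among replicates 1 and 2 was shared only in part by the replicate 3 pair, where 54.6% of the 4810 genes had the same direction. A later stage of the graphene oxide samples as the whole difference is argued against by 15 of 25 hepatocyte genes, all higher in control replicate 3 than in control replicate 1, that fell with graphene oxide, although across genes the difference of graphene oxide replicate 2 from control replicate 2 correlated with that of control replicate 3 from control replicate 1 (Spearman 0.28, Pearson 0.14), so a later stage as part of it stays open. A different time of day stays open, because per1a and nr1d1 rose but the median log2 fold change of 6 arntl, clock and npas2 genes, which oscillate in antiphase, was 0.0070. Whether replicates 1 and 2 of a group came from 1 pool stays open at a chi-square per degree of freedom of up to 1.62, and such a pool could hold differences unrelated to treatment. An effect of graphene oxide that depends on the stage or batch of the fish was not tested apart from these and stays open.

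For the count of genes, 10 of the 10 splits of the 6 libraries gave as many as the real split, which gave 0, and the highest other split gave 0. No split can give fewer than 0, so that share was fixed in advance and tells nothing. For the count of lists, 6 of the 10 splits gave as many as the real 5, and the highest other split gave 30. With 10 splits no share under 0.05 can be reached. The 4 splits that kept the replicate 3 libraries together gave 26 to 30 lists, which points to the structure of the samples. Among the other splits that parted all 3 pairs the counts were 7, 2 and 3.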

How the results depend on the processing

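Some alternatives (DESeq2, limma on FPKM, replicates 1 and 2 alone, log2 CPM for the lists, an estimated correlation with the block) were chosen after seeing the data, and the cause of a change was not tested unless given. Of 20 alternatives chosen before the data were examined, 19 also gave 0 genes, each left-out library and the replicate block included. The count was 1956 with array quality weights in limma, 10 with DESeq2, 61 with DESeq2 and the replicate block and 4810 for replicates 1 and 2 alone. The weighted fit gave list medians close to those of replicates 1 and 2 alone, so the 1956 may rest largely on their small spread. The 5 lists became 3 at a mean FPKM of at least 5, where fewer genes were tested, 10 with TPM, 9 without vitellogenin, pancreas and erythrocyte genes, 9 with the replicate block, 28 with a vitellogenin covariate, 9 with array weights and 11 for replicates 1 and 2 alone. Of the genes behind the covariate, vtg1 had 12 counts in control replicate 3 and at most 3 elsewhere. The 28 lists are therefore uncertain. An estimated correlation, fry, and an estimated correlation with the block each gave 0 lists. Leaving out a library gave 5 to 17 lists. Adjusted over the list alone, 3 members of 2 fixed lists passed without the replicate block and 68 members of 18 lists with it, 56 higher and 12 lower, and 0 and 37 members of the lists written later. Apart from these, the 4 fixed lists and the neural list it added, the eye list in fry and the calls of DESeq2, the block changed no call of a list or a named gene. Robust empirical Bayes was not run for the lists, since camera has no such setting. Among replicates 1 and 2, the 4810 genes became 2047 with DESeq2, 2468 with limma, 610 at 2-fold or more, and 3037 to 3855 without a library.

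Of 931 values of 41 named genes under alternatives, 809 kept their direction without a call, 69 kept it and passed, and 53 turned, in 9 genes, none of them past the main test. The log2 fold change of sod1 was 0.01 and became -0.023 and -0.021 with pseudocounts of 0.1 and 5, -0.022 in limma with and without the block, -0.038 with the replicate block, -0.042 with DESeq2 and the block, -0.095 with array weights and -0.14 for replicates 1 and 2. In the same order fabp10a, at 0.01, became -0.27, -0.18, -0.25, -0.069, -0.12, -0.34 and -0.40, and try, at 0.05, became -0.31, -0.11, -0.24, -0.092, -0.15, -0.36 and -0.44. With quantile normalization fabp10a and try were at -0.29 and -0.27. The log2 fold change of cat was 0.0023 without a filter, 0.0069 at a mean FPKM of at least 5, 0.023 with library totals, 8.6e-05 without the removed lists and 0.65 with the covariate. Leaving out a library gave -0.12 to 0.42 for il1b, -0.17 to 0.47 for pparaa, -0.48 to 1.28 for pparab, -0.45 to 0.31 for sod1, -0.69 to 0.56 for cat, -5.22 to 4.82 for fabp10a, -6.70 to 6.28 for try, -0.22 to 1.13 for mpx and -0.25 to 0.65 for mpeg1.1, the ends for all but il1b without a replicate 3 library. The fibroblast list median without a library was 0.10 to 0.46, against 0.26, with the camera direction turned without graphene oxide replicate 3. The fibroblast call ended, with the direction kept, without control replicate 1 (0.12) or 2 (0.11), and also where the median was larger, at a mean FPKM of at least 5 (0.27), with TPM (0.38) and without the removed lists (0.38). The endothelial call, at a median of 0.20, ended without control replicate 1 (0.10), control replicate 2 (0.07) and graphene oxide replicate 3 (0.05), with a pseudocount of 5 (0.10), at a mean FPKM of at least 5 (0.26), with TPM (0.30) and without the removed lists (0.31). The endothelial median rose to 0.56 without control replicate 3 and to 0.57 with the vitellogenin covariate. The cholesterol call ended without graphene oxide replicate 3 (0.06, against 0.18) and for replicates 1 and 2 alone (0.22). The cholesterol median rose to 0.33 without control replicate 3 and to 0.35 with the covariate. Of 90 list medians under alternatives 75 stayed past the threshold in the same direction. All 272 values of the 25 genes named among replicates 1 and 2 stayed past the threshold in the same direction. Those fits reused the libraries from which the genes were chosen, so this is no independent support. In simulated data with the spread of all 6 libraries the test recovered 1% of 2-fold changes. With replicate 3 set apart it recovered 11% without the block and 93% with it. Both hold at the small spread of replicates 1 and 2 and with equal effects in all pairs. Totals of 9739760 to 12998273 counts leave genes near 1 CPM, such as il1b, with few counts.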

Other observations

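The tests here were chosen after the data were examined. Eye transcripts had lower medians with graphene oxide in all 3 pairs. Of 37 photoreceptor and eye genes 32 had a negative log2 fold change, with medians of -0.27, -0.31 and -0.29 in pairs 1, 2 and 3, and camera gave an adjusted p of 1.55e-11 over the added lists, 0.334 with an estimated correlation. With the replicate block, 17 of the 37 genes, all lower, passed when adjusted over the list alone and 0 over all genes, and fry gave an adjusted p of 0.0223 with the block and 0.578 without it. Camera with the block gave adjusted p = 0.11 with an estimated correlation. The green cone opsin opn1mw1 was at 533, 518 and 615 CPM with graphene oxide against 813, 797 and 821 CPM in control.

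Lens crystallins had medians of 0.41, 0.47 and -0.25 in pairs 1, 2 and 3 (adjusted p = 9.93e-06 over all libraries, 0.442 with an estimated correlation), and cartilage and notochord genes 0.66, 0.60 and 0.02 (1.2e-05, 0.442 with an estimated correlation). Circadian clock genes had 0.51, 0.41 and -0.10 (9.93e-06, 0.442 with an estimated correlation) and larval globins 0.54, 0.57 and 0.17 (0.000349, 0.334 with an estimated correlation). Skeletal muscle genes had -0.18, -0.17 and 0.07 (0.0103, 0.456 with an estimated correlation), epidermis genes -0.02, -0.06 and -0.36 (0.00349, 0.442 with an estimated correlation) and neural genes -0.13, -0.11 and -0.05 (0.139, 0.74 with an estimated correlation). The neural list passed with the replicate block, at 0.0114, where adjusted p = 0.357 with an estimated correlation. Among replicates 1 and 2 alone, camera with an estimated correlation gave adjusted p = 0.0356 for the eye, lens, cartilage and clock lists. It gave 0.0535 for globins, 0.0782 for muscle and for neural genes and 0.235 for epidermis. These lists were written after the same data were examined, and the spread was that of replicates 1 and 2 only. Of the larval globins 4 also stand in the fixed erythrocyte list, and 3 epidermis genes in the biliary list.

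In the antioxidant list 28 of 41 genes were higher with graphene oxide over all libraries and 33 in the replicate 3 pair. The count in that pair is not particular to this list. There 48 of 58 cell cycle genes and 26 of 31 iron handling genes were higher, while 17 of 46 ER stress genes were. Among replicates 1 and 2, 15 rose, 8 fell and 18 were not called, and the list did not pass (adjusted p = 0.304). Over all libraries 14 rose and 3 fell with the replicate block when adjusted over the list alone, with 0 past the test over all genes.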
